A study of Mus musculus with 10 samples.

How the data were processed

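Primary mouse embryonic fibroblasts that carried an Oct4-GFP reporter were infected with retroviruses for Jdp2, Glis1, Esrrb and Sall4 and then moved to an induction medium named iCD3. Messenger RNA was sequenced on a NextSeq 500 after 0, 1, 3, 5 and 7 days in that medium, here D0 to D7. Each day had 2 libraries, numbered replicate 1 and 2, which made 10 libraries in all, and the series text speaks of independent experiments. Nothing further in the labels says which cultures the replicates came from, so the p-values measure the spread between these libraries, which may in part be technical.

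Per the submitters' processing notes, the reads were handled with bcl2fastq, Bowtie2 and RSEM on the mouse build mm10; versions and the gene annotation release are not given in the sources used here. Per the file headers, each file is an RSEM table of genes with expected counts, TPM and FPKM, which RSEM computed for the authors. The deposited expected counts are estimates that need not be whole and are not normalised. The deposited TPM values were used in an alternative only, and the deposited FPKM values were not used. The labels name 2 library kits and 2 sequencing kits for every sample without saying which library had which. RSEM shares reads between near-identical genes by estimation, so values of gene families such as Zscan4, Tuba3, Sprr2a and Zfp600 are uncertain, as are those of overlapping genes such as Pakap. Whether strand was used in counting is not given in the sources used here.

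The files held the same 54752 Ensembl genes. Gene names came from GENCODE release M21 on GRCm38, the assembly that mm10 names, and 54723 identifiers matched. The 29 without a name took 0.000602% to 0.00179% of a library's counts, and coordinates below are 1-based from that release. The libraries held 2176457 to 4335931 estimated counts in replicate 1 and 1329377 to 1492105 in replicate 2. The mean fragment length implied by the deposited effective lengths was 135 to 158 bases in replicate 1 and 198 to 203 bases in replicate 2. Replicates of a day differed by more than counting noise on every day (chi-square per gene 7.75 to 23), so none was counted as a repeat deposit of another. Counting intervals and floors below cover counting error only, since reads without molecular identifiers are not independent molecules. A gene at 0 on one day was given a floor of 3 counts over the libraries of that day, which makes a fold a lower bound, and a gene with 1 to 3 counts was given its ratio with an exact 95% counting interval. These folds and ratios pool the counts of a day's libraries, which gives the deeper replicate 1 more weight, so they differ from ratios of mean CPM.

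Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood F test, limma 3.58.1, R 4.3.3). Genes were kept by edgeR's filter with a minimum count of 10, which left 12752, and libraries were scaled by TMM. A single model with a term per day was fitted to all 10 libraries, so that all days share an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p below without another name comes from this test. Neighbouring days were compared, as were D7 with D0 and D7 with D3. The last of these shares no library with D1 against D0, so genes that changed early and late were counted from that pair and set beside the number that independent lists of the same sizes would share. An SE is the absolute log2 change divided by the square root of the F statistic, not a standard error fitted by the model. CPM values are edgeR's, from TMM-scaled library totals, given as mean ± SD with n = 2. Principal components were taken from log2 CPM (prior count 2) of the 1000 most variable genes.

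A set of 40 gene lists with 742 entries was fixed before the data were examined, along with the tests of the comparisons and the rule for named genes. In total 569 list members were tested, and the 35 lists with at least 5 tested members entered camera with a preset correlation of 0.01, adjusted over 35 lists and 5 comparisons (175 tests). A member silent on the early days passed the filter only through later days. The tested members of lists that hold such genes were therefore in part selected for a rise. Camera with a correlation estimated from the data, in the fit without the replicate number, called no list in any comparison. Its adjusted p stands beside each list call. Shifts shared by the libraries of a replicate number enter that correlation. Medians of lists are log2 changes with genes at or under the 3-count floor set to their bound. In the section on how the results depend on the processing, they are medians of the fitted log2 changes without that bound. The lists of macrophage, erythroid, skeletal muscle, adipocyte and keratinocyte markers had too few tested members.

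Named genes were a panel of 25. They also included the 12 called genes with the largest change up and the 12 down for D7 against D0, and the 5 up and 5 down for each step. These needed a mean of at least 5 CPM over all libraries, no overlap between the libraries of the 2 days and a symbol that is not a predicted or numbered model. From each list up to 4 called members with the largest change were named, or the 2 most abundant where none was called. For genes that changed early and in the opposite direction later, the 5 per direction with the smallest larger-of-2 adjusted p were named.

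Whether the replicate numbers pair the libraries was checked from the deviations of the replicate 1 libraries from their day means. Between days these correlated across genes at 0.27 to 0.44 in all 10 pairs of days. The third principal component, with 10% of the variance, also separated the numbers, so the numbers were taken to pair the libraries. Fragment length and library total split by number too. A shared library difference would therefore give the same pattern, and the check cannot assign the pairing to the independent experiments. The planned fit without the replicate number remained the main one, and a count of called genes or list members with the number as a block stands beside it where it differed by over 1.5 times. On simulated counts for D7 against D0 over 12752 genes, the same steps recovered 10% of 60 genes changed 2-fold, 60% of 70 changed 4-fold and 94.3% of 70 changed 8-fold, and called 6 unchanged genes. Simulated 4-fold reversals between the early and late comparisons were recovered for 36 of 60 genes. Far fewer genes changed in the simulation than in the data, which makes the adjusted threshold stricter, so these shares need not hold for the data.

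The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (at least 5 CPM in at least 2 libraries), the replicate number as a block, fits of only the days compared, thinning to the smallest library, an added 2-fold threshold and each library left out in turn. A fit of protein-coding genes alone was added after the data had been seen, as was the split of the blocked early and late counts by direction. Thinning in these alternatives was a single random draw, so a call near the threshold could differ in another draw. Groups of 2 libraries are too small for regrouping the samples, which was therefore not done. Figures were drawn with matplotlib 3.10.9.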

Results

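Gene expression was followed in mouse embryonic fibroblasts, connective tissue cells taken from embryos, that received Jdp2, Glis1, Esrrb and Sall4 by retrovirus. The series title gives induction of pluripotent stem cells as the aim. Each of 5 days in the induction medium (D0, D1, D3, D5 and D7) had 2 libraries, and 12752 of 54752 genes were tested. Library totals ran from 2176457 (D0) to 4335931 (D7) estimated counts in replicate 1 and from 1329377 (D5) to 1492105 (D0) in replicate 2. At that depth 3 counts stood for 0.653 to 2.32 CPM, so low genes were measured less precisely in replicate 2. Mitochondrial messenger RNAs took 2.17% to 5.36% of the counts. A ribosomal RNA gene, CT010467.1, took 0.8% of the counts in D7 replicate 1 and 0.0428% to 0.14% in the other libraries.

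Within each replicate number the days lay in order along the first principal component, which held 55% of the variance, from -58.5 and -64.2 at D0 to 57.5 and 41.4 at D7 (replicates 1 and 2). D5 replicate 1 lay at 50, beyond D7 replicate 2, and D5 replicate 2 at 25.9. The second component held 19.4% and set D0 and D7 (19.3 to 32.4) apart from D1 and D3 (-37.2 to -14.4). Across genes, the log2 change from D0 to D7 in replicate 1 correlated with that in replicate 2 at a Pearson r of 0.83 (Spearman 0.79). For the steps, r was 0.67 for D1 against D0, 0.42 for D3 against D1, 0.26 for D5 against D3 and 0.36 for D7 against D5. Genes are not independent replicates, so no p was attached. With log2 TPM or a larger set of variable genes the first component held 49.3% and 47.4%.

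**Figure D1:**
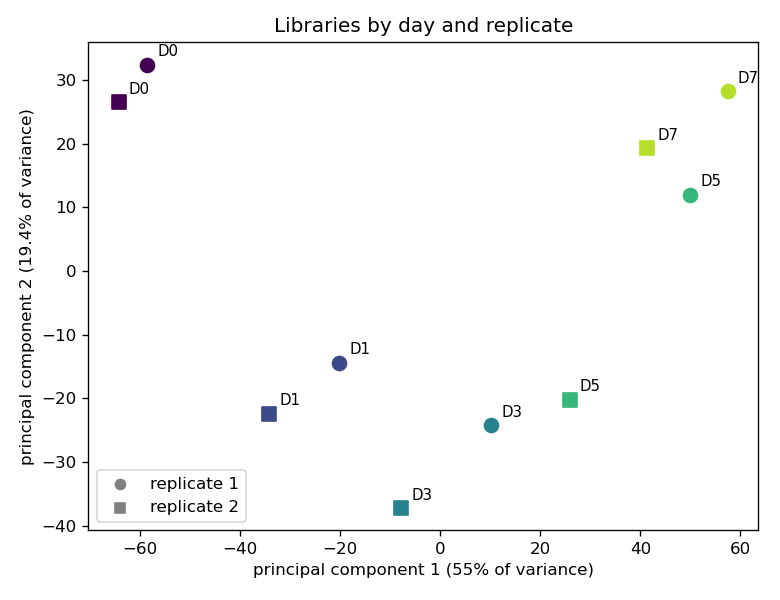
First and second principal components (55% and 19.4% of the variance, component scores on both axes) of the 1000 most variable genes, 1 point per library, coloured and marked by day, with circles for replicate 1 and squares for replicate 2. D5 replicate 1 (50 on the first component) lies nearer to the D7 libraries (57.5 and 41.4) than D5 replicate 2 (25.9).

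Of the delivered factors 3 fell over the course. Total reads of Esrrb, an orphan nuclear receptor of pluripotent cells, went from 1710 ± 182 CPM at D0 and 2400 ± 688 at D3 to 591 ± 22 at D7. Sall4, a zinc finger factor of early embryos, went from 2370 ± 430 to 749 ± 6.71 CPM between D0 and D7, and Jdp2, a repressor of the AP-1 family, from 756 ± 276 to 255 ± 116 CPM. Between D0 and D7 the log2 changes were -1.53 (SE 0.35, adjusted p = 0.0119) for Esrrb, -1.66 (SE 0.36, adjusted p = 0.00959) for Sall4 and -1.56 (SE 0.48, adjusted p = 0.0442) for Jdp2. Glis1, a Kruppel-like zinc finger factor, had 141 ± 93.1 CPM at D0 and 56.6 ± 19.4 at D7 and was not called (log2 change -1.32, SE 0.74, adjusted p = 0.261, or 0.0199 with the replicate number as a block). Its change ran from -1.88 without D0 replicate 1 to -0.37 without D0 replicate 2. None of the 4 was called in any step between neighbouring days, so the steps do not date the fall. Against D3, the D7 changes were -2.02 (adjusted p = 0.0152) for Esrrb, -1.65 (0.0302) for Sall4, -2.23 (0.0302) for Jdp2 and -1.73 (0.194, blocked 0.0134) for Glis1. The counts cannot separate viral from endogenous transcripts. These genes are Jdp2 (ENSMUSG00000034271, chromosome 12, 85599027 to 85639878), Glis1 (ENSMUSG00000034762, chromosome 4, 107434591 to 107635061), Esrrb (ENSMUSG00000021255, chromosome 12, 86361117 to 86521628) and Sall4 (ENSMUSG00000027547, chromosome 2, 168748332 to 168767943), on GRCm38. The D7 against D0 calls were lost without D7 replicate 1 (adjusted p = 0.0882 for Esrrb, 0.0812 for Sall4, 0.0682 for Jdp2), D7 replicate 2 (0.079, 0.0646 and 0.249) or D0 replicate 2 (0.0799, 0.0764 and 0.0709). For Jdp2 the call also went without D0 replicate 1 (0.257), D3 replicate 1 (0.0588) or D3 replicate 2 (0.051), and with upper-quartile scaling (0.0633), thinning (0.0541) or the stricter filter (0.05).

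**Figure D2:**
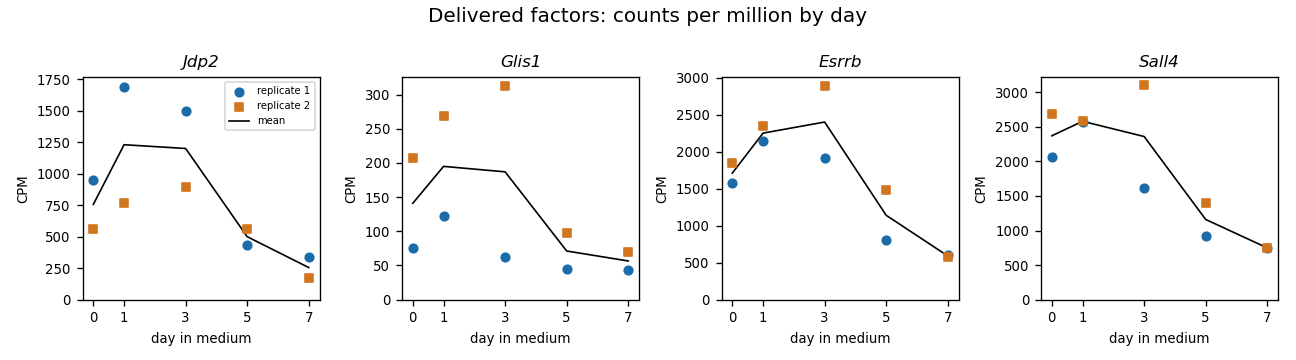
CPM (vertical axes, from 0) of the 4 delivered factors against day in the medium, with 1 point per library (blue circles replicate 1, orange squares replicate 2) and a line through the means of 2. Sall4 and Esrrb stand at 2370 and 1710 CPM at D0 and at 749 and 591 at D7.

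Comparing D7 with D0 asked which genes differed between infected fibroblasts and the end of the course. Among the largest increases, Tdgf1, a Nodal co-receptor, was at 0 counts at D0 and 132 ± 60 CPM at D7, at least 173-fold higher. Dazl, a germ cell RNA-binding protein, was at least 128-fold higher, and Lin28a, a regulator of let-7 microRNAs, at least 77.1-fold higher. Dnmt3l, a cofactor of DNA methylation, Dppa4 and Dppa2 were at least 70.5-, 62.2- and 68.5-fold higher. Zfp600, Fam169a, Trap1a, Rbmxl2, Morc1 and Cdx1, a homeobox gene of the posterior embryo, were likewise at 0 at D0 and at least 75.7-, 68.9-, 60.2-, 60.6-, 64.4- and 63.5-fold higher. Among the largest decreases, Acta2, smooth muscle actin, fell from 4760 to 44.2 ± 35.1 CPM (log2 change -6.80, SE 0.81), Lox, a collagen cross-linker, from 753 to 5.57 ± 3.27 (-7.24, SE 0.52), and Cnn1, calponin, from 350 to 1.86 ± 0.163 (-7.55, SE 0.59). Ccn5 and Foxs1 were at 0 at D7, at least 107- and 55.5-fold lower. Actg2, Ccl7 and Lhx9 had 1 count left at D7, with ratios of 0.00119 (3.01e-05 to 0.00667), 0.00485 (0.000122 to 0.0275) and 0.0115 (0.000285 to 0.0673). Prss23, Ltbp2, Cspg4 and Inhba, a subunit of activin, fell by 6.06, 6.47, 6.14 and 6.10 on the log2 scale. The adjusted p of these 24 genes ran up to 0.00524, reached by Dazl. All 24 remained called without each library, and Dazl was not called with DESeq2 (adjusted p = 0.163).

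The panel gave the course of familiar genes. Sox2, a core pluripotency factor, rose early, from 6.79 ± 0.0804 CPM at D0 to 79.5 ± 15.8 at D1 and 175 ± 46.8 at D7 (D1 against D0 log2 change 3.54, SE 0.43, adjusted p = 0.002). Pou5f1, which encodes Oct4, had 4.36 ± 4.16 CPM at D1, 83.6 ± 75 at D3 and 397 ± 48.6 at D5. It was higher at D7 than at D0 (331 ± 5.96 against 1.87 ± 2.65 CPM, log2 change 7.70, SE 1.02, adjusted p = 0.000727), as was Nanog (193 ± 47.8 CPM at D7, ratio 355 with an interval of 98 to 2930). Zfp42 (79.9 ± 34 CPM at D7), Utf1 (84.2 ± 4.84) and Dppa5a (334 ± 34) had ratios of 155 (42.8 to 1290), 145 (40 to 1200) and 1170 (210 to 46300). These sizes rest on few counts at D0: without D0 replicate 1 or 2 the log2 change was 6.45 or 12.74 for Pou5f1, 6.97 or 11.96 for Nanog, 10.65 or 6.35 for Zfp42, 5.77 or 10.77 for Utf1 and 8.71 or 12.75 for Dppa5a. E-cadherin (Cdh1) rose from 15.4 ± 3.8 to 181 ± 29.4 CPM (log2 change 3.53, SE 0.36, adjusted p = 0.000193) and Epcam to 123 ± 26.6 CPM (ratio 446, 79.9 to 17700, log2 change 7.27 or 11.31 without D0 replicate 1 or 2). Of the fibroblast genes in the panel, Col1a1 fell by 4.82 (SE 0.49, adjusted p = 0.000209), Thy1 by 4.10 (SE 0.32, 7.38e-05), Postn by 2.63 (SE 0.34) and Prrx1 by 2.23 (SE 0.39) on the log2 scale. Dnmt3b and Tet1, which add and oxidise DNA methyl groups, rose to 131 ± 75.3 and 155 ± 49.6 CPM. The mesenchymal regulators Snai2 (32.9 ± 7.4 and 31.6 ± 20.4 CPM at D0 and D7, adjusted p = 0.901) and Twist1 (68.1 ± 10.6 and 65.9 ± 36.9 CPM, 0.948) were not called, and neither was Klf4 (39.7 ± 10.5 and 60 ± 7.73 CPM, 0.362). Of 21 panel genes called, 15 remained called without each library. The exceptions were Esrrb, Sall4 and Jdp2, Myc (log2 change -1.63, adjusted p = 0.0482, up to 0.26 without D0 replicate 2), Zeb1 (-0.98, 0.0406, up to 0.216 without D7 replicate 1) and Tet1 (4.22, 0.00412, and 0.0524 without D0 replicate 1). Myc and Zeb1 were also lost with upper-quartile scaling (0.0586 and 0.0675) with thinning (0.0629 and 0.0626) and with the stricter filter (0.0525 and 0.051). Myc was lost with RLE scaling (0.0525), and Zeb1 with DESeq2 (0.0674) and no filter (0.117).

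**Figure D3:**
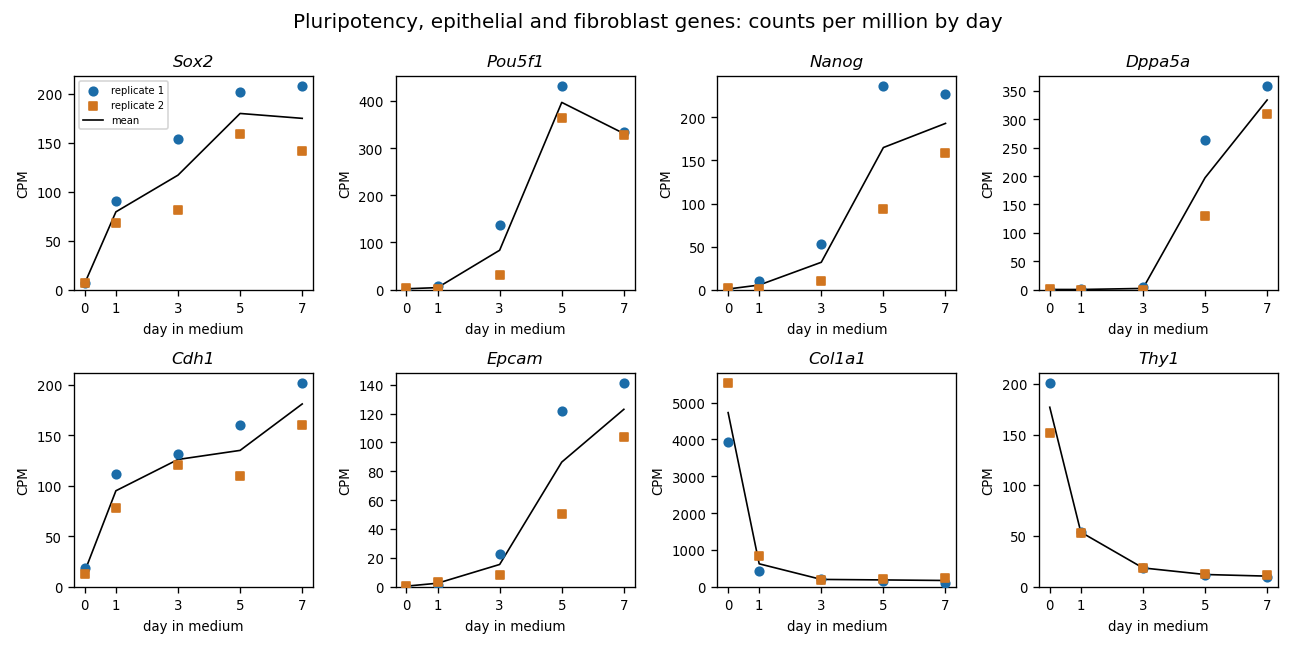
CPM (vertical axes, from 0) of 8 panel genes against day in the medium, 1 point per library (blue circles replicate 1, orange squares replicate 2) with a line through the means of 2. Sox2 and Cdh1 reach 79.5 and 95 CPM by D1, Dppa5a is at 2.19 CPM at D3 and 197 at D5, and Col1a1 goes from 4730 to 621 CPM between D0 and D1.

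Among gene groups, the pluripotency network, with the delivered Esrrb and Sall4 left out of the list, rose between D0 and D7. Of its 33 tested members 28 rose and none fell (31 adjusted over the list alone), with a median log2 change of 4.99 (camera adjusted p = 2.11e-35, adjusted p = 0.154 with an estimated correlation). Epithelial junction genes and regulators had 16 of 24 higher and none lower (21 adjusted over the list alone, median 3.37, camera adjusted p = 3.98e-14, adjusted p = 0.0602 with an estimated correlation), among them the tight junction genes Cldn6 (at least 21.4-fold higher) and Tjp3 (at least 21.5-fold) and the splicing regulator Esrp1 (at least 15.8-fold). Germline genes held silent by DNA methylation had 8 of 9 higher (8 adjusted over the list alone, median 3.47, camera adjusted p = 4.52e-06, adjusted p = 0.271 with an estimated correlation), with Ddx4, an RNA helicase, at least 11-fold and Rpl10l at least 16-fold higher. Members silent at D0 passed the filter only through a later day, so this share was partly fixed in advance. The same limit applies to the genes of the 2-cell embryo below. Wnt targets had 10 of 14 higher and 2 lower (11 and 2 adjusted over the list alone, median 2.37, camera adjusted p = 1.67e-06, adjusted p = 0.285 with an estimated correlation), including Notum (log2 change 4.95, SE 0.77) and Sp5 (4.13, SE 0.69). Of 5 tested genes of the 2-cell embryo 3 rose (5 adjusted over the list alone, median 3.01, camera adjusted p = 0.00339, adjusted p = 0.249 with an estimated correlation), with Zscan4c at least 15.3-fold higher, subject to reads shared within its family. None of the 3 kept its call without each library, and Tmem92 and Zscan4e were not called with DESeq2 (adjusted p = 0.0773 and 0.0525). Glycolysis genes had 9 of 17 higher (11 adjusted over the list alone, median 1.07, camera adjusted p = 3.17e-06, adjusted p = 0.271 with an estimated correlation), led by Aldoc (4.45 to 98.4 ± 28.5 CPM) and the kinase Pdk1 (19.4 to 337 ± 109 CPM).

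Matrix and contractile genes fell. All 18 tested contractile and serum response factor targets fell (18 adjusted over the list alone, median -4.43, camera adjusted p = 8.65e-30, adjusted p = 0.128 with an estimated correlation), Tagln, transgelin, from 2630 to 41.5 ± 36.2 CPM. Of 28 collagen and matrix genes 24 fell and none rose (25 adjusted over the list alone, median -3.36, camera adjusted p = 1.5e-41, adjusted p = 0.0602 with an estimated correlation), among them Thbs1, thrombospondin (3750 to 57.7 ± 31.8 CPM), and the collagen Col12a1 (1660 to 42.9 ± 11.8). Fibroblast markers had 9 of 14 lower (10 adjusted over the list alone, median -3.46, camera adjusted p = 1.54e-11, adjusted p = 0.213 with an estimated correlation), Fbln2 from 1960 to 102 ± 65.9 CPM. Mesenchymal regulators and markers had 12 of 19 lower (13 adjusted over the list alone, median -1.81, camera adjusted p = 1.04e-09, adjusted p = 0.263 with an estimated correlation), with Foxc2 and Tgfb3 down by -4.70 (SE 0.45) and -4.11 (SE 0.63). TGF-beta targets had 5 of 10 lower (6 adjusted over the list alone, median -1.97, camera adjusted p = 2.63e-08, adjusted p = 0.163 with an estimated correlation), among them Pmepa1 (160 to 15 ± 2.08 CPM). Inflammatory and secretory genes had 8 of 13 lower and 1 higher (8 and 1 adjusted over the list alone, median -3.51, camera adjusted p = 5.64e-07, adjusted p = 0.263 with an estimated correlation), such as the chemokine Ccl2 (232 to 4.37 ± 3.11 CPM) and Ptgs2 (103 to 1.97 ± 0.936). AP-1 family genes without Jdp2 had 4 of 11 lower (7 with the replicate number as a block, 5 adjusted over the list alone, median -1.56, camera adjusted p = 0.00274, adjusted p = 0.64 with an estimated correlation), with Fosl1 and Junb down by -4.07 (SE 0.71) and -3.60 (SE 0.76). Hox genes, which pattern the body axis, had 12 of 30 lower and 2 higher (15 and 2 adjusted over the list alone, median -1.59, camera adjusted p = 1.98e-05, adjusted p = 0.413 with an estimated correlation), Hoxd13 and Hoxc8 lower and Hoxb13 higher, the last not with limma-voom (0.0943) or thinning (0.0569). The call of Hoxb13 was also lost without either D0 replicate or without D7 replicate 1. Targets of p53 and inhibitors of cell cycle kinases had 6 of 22 lower and 3 higher (12 and 3 with the block, 10 and 3 adjusted over the list alone), with Mdm2 going from 369 to 112 ± 30.5 CPM (median of the list -0.91, camera adjusted p = 0.0413, adjusted p = 0.556 with an estimated correlation). That list call was lost without D7 replicate 1 (0.248), D0 replicate 1 (0.0645), D5 replicate 1 (0.0559), D5 replicate 2 (0.0542) or D3 replicate 1 (0.0508).

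**Figure D4:**
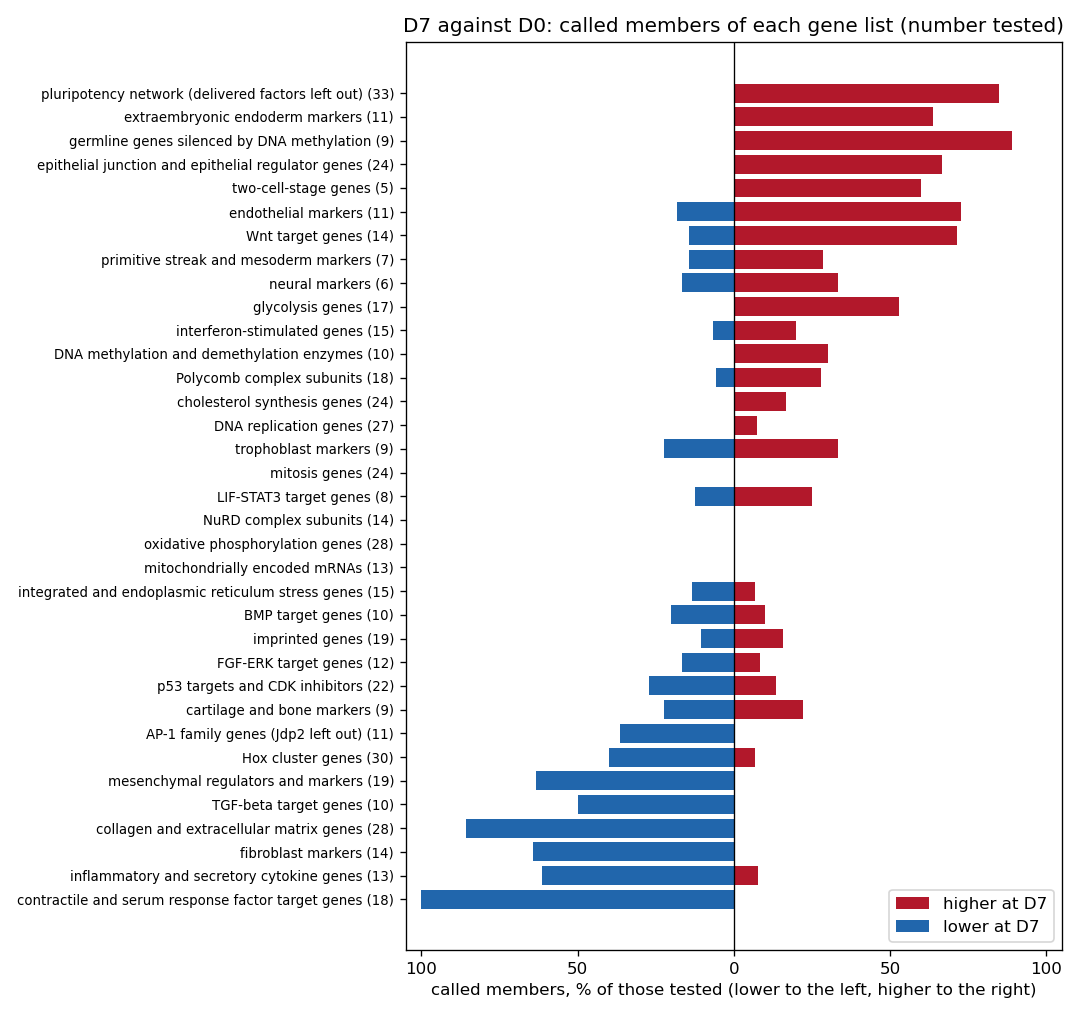
Share of each list's tested members (number in brackets) called higher (red, right) or lower (blue, left) at D7 than at D0, in percent, for the 35 lists tested, sorted by median change. All 18 contractile genes are lower and 28 of 33 pluripotency genes higher, while mitosis, NuRD, oxidative phosphorylation and mitochondrial genes have no called member.

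Among chromatin and cell cycle groups, DNA methylation and demethylation enzymes had 3 of 10 higher, Dnmt3b, Tet1 and Tet2 (7 with the block, 7 adjusted over the list alone, median 0.93, camera adjusted p = 0.000524, adjusted p = 0.285 with an estimated correlation). Polycomb subunits had 5 of 18 higher and 1 lower (10 and 2 with the block, 8 and 1 adjusted over the list alone, median 0.86, camera adjusted p = 0.0158, adjusted p = 0.285 with an estimated correlation), Jarid2 from 30 to 238 ± 77.1 CPM and Cbx7 from 7.77 to 60.6 ± 17. No member of the NuRD repressor complex was called among 14 (1 lower with the block, camera adjusted p = 0.793), Chd4 standing at 529 and 596 ± 117 CPM. DNA replication genes had 2 of 27 higher, Cdt1 (log2 change 1.66, SE 0.35) and Mcm2 (1.08, SE 0.30), or 7 higher and 1 lower with the block. Neither gene kept its call without each library, and without D0 replicate 1 their changes were 1.39 and 0.81. The list was higher by camera (1 adjusted over the list alone, median 0.41, camera adjusted p = 0.0355, adjusted p = 0.734 with an estimated correlation), a call lost without D7 replicate 1 (0.0837) or D0 replicate 1 (0.0627). None of 24 mitosis genes was called (1 lower with the block, camera adjusted p = 0.909), with Mki67 at 357 and 382 ± 34.7 CPM at D0 and D7. Oxidative phosphorylation genes had no call among 28 (camera adjusted p = 0.793) and mitochondrially encoded messenger RNAs none among 13 (0.97). Cholesterol synthesis genes had 4 of 24 higher (11 with the block, 4 adjusted over the list alone, median 0.69, camera adjusted p = 0.00773, adjusted p = 0.689 with an estimated correlation), led by Dhcr7 (28.3 to 115 ± 8.7 CPM), and that list call was lost without D7 replicate 1 (0.0994).

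In all, 2278 genes differed between D7 and D0, 17.9% of those tested, 1167 higher and 1111 lower. Each moved the same way in both replicates, but a call from 2 libraries per day nearly requires that, so it is no separate support. With the replicate number as a block 3629 were called (1884 higher, 1745 lower), including all 2278. Without D0 replicate 1 or 2 the count was 945 or 1041, and without D7 replicate 1 or 2 it was 841 or 1443. More were lower than higher with limma-voom (1107 higher, 1204 lower), narrowly with DESeq2 (1111 and 1115), and without D0 replicate 1. Few changes under 2-fold were called, since 2233 of the 2278 genes changed at least 2-fold. The 10% of simulated 2-fold changes that were recovered need not hold here, since far fewer genes changed in the simulation.

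The first step, D1 against D0, asked what changed in the first day of medium. Cnn1, calponin of contractile cells, fell from 350 to 9.55 ± 3.6 CPM (log2 change -5.26, SE 0.51, adjusted p = 0.000968), Lmod1, leiomodin, from 53 to 1.47 ± 0.0697 (-5.11, SE 0.63), Ccn5 from 51.3 to 1.12 ± 0.573 and Cavin2, of caveolae, from 44.7 to 1.27 ± 0.788. Pakap was at 0 at D1, at least 122-fold lower. Kcnj12 and Kcna2, which encode potassium channels, and Mixl1, a homeobox gene of the primitive streak, were at 0 at D0. Kcnj12 rose by at least 34.6-fold, Kcna2 by at least 26.9-fold, Mixl1 by at least 24.5-fold (22 ± 1.04 CPM), and C1ql2 and Cabp7, a calcium-binding protein, by at least 20.4- and 17.8-fold. Col1a1 fell by 2.93 (SE 0.45, adjusted p = 0.00477) and Thy1 by 1.72 (SE 0.28, 0.00593), and Cdh1 rose by 2.61 (SE 0.35, 0.00269). Of 28 matrix genes 18 fell (24 adjusted over the list alone, camera adjusted p = 1.27e-34, adjusted p = 0.0602 with an estimated correlation) and of 18 contractile genes 13 fell (18 adjusted over the list alone, 2.4e-31, adjusted p = 0.119 with an estimated correlation). Epithelial genes had 7 of 24 higher (13 adjusted over the list alone, 7.44e-10, adjusted p = 0.0602 with an estimated correlation) and Wnt targets 5 of 14 (10 adjusted over the list alone, 4.64e-10, adjusted p = 0.249 with an estimated correlation). In all 5 lists were higher and 10 lower by camera, and 0 with an estimated correlation. The test called 577 genes, 307 higher and 270 lower, or 1350 with the replicate number as a block and 1064 with no filter. Which direction had more calls was not stable: 207 were higher and 338 lower with limma-voom, 672 and 678 with the block, 53 and 67 without D0 replicate 1, and 125 and 44 without D1 replicate 1. The count was 120 or 170 without D0 replicate 1 or 2, 169 or 308 without D1 replicate 1 or 2, and 908 or 899 without D5 replicate 1 or 2. Without each library 6 of the 10 genes named by size remained called, all but Kcna2, Cabp7, C1ql2 and Ccn5, which were lost without D0 replicate 1 (adjusted p = 0.0523, 0.149, 0.155 and 0.0599). Cabp7 and C1ql2 were also lost without D0 replicate 2 (0.121 each) or D1 replicate 2 (0.0672 and 0.0548), and C1ql2 without D1 replicate 1 (0.0816). With limma-voom neither was called (0.0721 for Cabp7, 0.0815 for C1ql2).

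Between D1 and D3 only increases were called. Selenop, which encodes a secreted selenium carrier, went from 127 ± 73.6 to 1930 ± 163 CPM (log2 change 3.91, SE 0.43, adjusted p = 0.0116). Trh, the thyrotropin-releasing hormone precursor, went from 3.7 to 153 ± 98.7 CPM (5.11, SE 0.71, 0.0323), and Crybb1, a lens crystallin, from 1.62 to 70.9 ± 26.2 (5.34, SE 0.72, 0.0286). Klf2, a pluripotency factor, rose from 0.812 to 17.8 ± 6.24 CPM (4.35, SE 0.55, 0.0251), and Sprr2a2, of an epidermal gene family whose members share reads, from 3.66 to 79.5 ± 25. The others were Trpm1 (3.84, adjusted p = 0.0251) and Socs2 (2.39, 0.0286). Klf2 was the single called member of 33 in the pluripotency list (10 higher with the block, 17 adjusted over the list alone, median 1.73, camera adjusted p = 2.37e-21, adjusted p = 0.257 with an estimated correlation), and matrix genes had none of 28 called (10 lower with the block, 15 lower adjusted over the list alone, median -0.98, camera adjusted p = 3.16e-19, adjusted p = 0.0991 with an estimated correlation). By camera 2 lists were higher and 9 lower, and 0 with an estimated correlation. The 7 calls became 206 with the replicate number as a block (106 higher, 100 lower), 128 with DESeq2, 272 with no filter and 1 with limma-voom. The count was 3 without D0 replicate 1 or 2, 1 or 0 without D1 replicate 1 or 2, 0 or 4 without D3 replicate 1 or 2, 43 or 44 without D5 replicate 1 or 2 and 2 without D7 replicate 2. There 0 of the 5 genes named by size remained called without each library. With limma-voom Crybb1 (0.139), Trh (0.124), Sprr2a2 (0.0781) and Klf2 (0.127) were not called, and without D1 replicate 1 the change of Trh was 7.66 (0.194).

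From D3 to D5, Dppa5a, a marker of pluripotent cells, went from 2.19 ± 3.1 to 197 ± 95.6 CPM (log2 change 6.08, SE 0.71, adjusted p = 0.0178), Utf1 from 4.04 to 86.8 ± 16.7 (4.26, SE 0.61, 0.037) and Dppa4 from 1.1 to 36 ± 17 (4.85, SE 0.60, 0.037). Trap1a and Rbmxl2 had ratios of 147 (26.1 to 5850) and 66.9 (22.6 to 327). Among the other called genes, Alpl, the alkaline phosphatase used to stain pluripotent colonies, rose by 3.15 on the log2 scale (adjusted p = 0.0213), the lactate transporter Slc16a3 by 3.20 (0.0178) and Arid3b by 3.63 (0.0213). Ryr1, a calcium release channel of muscle, was the single gene to fall, from 383 ± 69.3 to 92.3 ± 0.706 CPM (-2.05, SE 0.29, 0.037). The pluripotency list had 3 of 33 higher (23 with the block, 27 adjusted over the list alone, median 2.98, camera adjusted p = 3.86e-46, adjusted p = 0.1 with an estimated correlation). Mitosis and DNA replication lists were higher by camera with no called member (6 and 5 higher with the block, 3 and 10 higher adjusted over the list alone, adjusted p = 6.83e-13 and 2.38e-12, and adjusted p = 0.285 and 0.249 with an estimated correlation). In total 11 lists were higher and 4 lower, and 0 with an estimated correlation. The 9 calls became 421 with the replicate number as a block (288 higher, 133 lower), 151 with DESeq2, 452 with no filter and 4 with limma-voom. Without D3 replicate 1, D3 replicate 2 or D5 replicate 1 the count was 0, without D7 replicate 1 or 2 it was 3, and without D5 replicate 2 it was 295. Of the 6 genes named by size 0 remained called without each library, and Ryr1 was also lost in a fit of those days alone (adjusted p = 0.117). With limma-voom Trap1a (0.0781), Dppa5a (0.0687), Dppa4 (0.0754) and Utf1 (0.0687) were not called, nor were Trap1a (0.079) and Dppa4 (0.0812) with thinning. Without D3 replicate 1 the change of Dppa5a was 11.86 (0.107) and that of Trap1a 8.94 (0.174).

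No gene was called between D5 and D7. Pou5f1 stood at 397 ± 48.6 and 331 ± 5.96 CPM, Nanog at 165 ± 101 and 193 ± 47.8, and Dnmt3l at 16.1 ± 8.61 and 53.7 ± 24.9. By camera the 5 genes of the 2-cell embryo were higher (median 4.62, adjusted p = 3.57e-15, adjusted p = 0.103 with an estimated correlation, 5 adjusted over the list alone), as were germline genes (median 1.84, 2.68e-10, adjusted p = 0.0983 with an estimated correlation, 3 adjusted over the list alone). In all 6 lists were higher and 6 lower, and 0 with an estimated correlation. With edgeR 810 genes had an unadjusted p under 0.05, and limma-voom also called 0. DESeq2 called 30, the fit with no filter 176 and the fit with the replicate number as a block 20 (16 higher, 4 lower), and the count was 232 without D5 replicate 1.

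Over the whole course 2436 genes, 19.1% of those tested, differed on at least 1 day, or 4455 with the replicate number as a block and 4139 with no filter. The count was 1283 or 1243 without D0 replicate 1 or 2 and 1414 without D7 replicate 1. Between D3 and D7 685 genes differed, 391 higher and 294 lower, or 2351 with the block (1212 higher, 1139 lower), 1664 with no filter and 1150 in a fit of those days alone. That count was 12 or 4 without D3 replicate 1 or 2, 5 or 129 without D7 replicate 1 or 2, 1546 or 1557 without D5 replicate 1 or 2 and 404 or 400 without D0 replicate 1 or 2.

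A number of genes changed in the first day and in the opposite direction later, not always back to their D0 level. Ass1, argininosuccinate synthase of arginine production, rose from 459 ± 14.2 CPM at D0 to 3710 ± 283 at D1, stood at 4850 ± 1280 at D3 and fell to 482 ± 129 at D7. Ryr1 went from 3.21 to 167 ± 45.4, 383 ± 69.3 and 47.6 ± 1.31 CPM on those days, and Car4, a carbonic anhydrase, from 8.16 to 206 ± 141, 441 ± 44.2 and 37.2 ± 3.11. Rph3a, of synaptic vesicles, and Dlx4, a homeobox gene, rose to 25.7 ± 4.13 and 39.5 ± 12.6 CPM at D1 and were at 0.872 ± 0.304 and 2.94 ± 1.37 at D7. In the other direction, Klf2 fell from 15.7 ± 6.33 to 0.812 ± 0.142 CPM in the first day. It was back near its D0 level by D3, so its rise to 121 ± 7.38 at D7 was a further increase. Slc16a3 went from 67 ± 11.1 to 21.9 ± 1.25, 9.13 ± 4.48 and 216 ± 51.4 CPM at D0, D1, D3 and D7. Limch1, Akap12, an anchor of protein kinase A, and P4ha2, a collagen prolyl hydroxylase, also fell in the first day and were higher at D7 than at D3, but stood at 22, 280 and 35.7 CPM at D7 against 54.1, 481 and 53.7 at D0. The late call of P4ha2 was lost with thinning (0.0627). Of the genes called higher at D1 than D0, 89 were called lower at D7 than D3, where independent lists would share 7.08. Genes lower and then higher numbered 19 (8.28 from independent lists), higher both times 5 (9.41) and lower both times 6 (6.22). With the replicate number as a block the ratios to independent lists were smaller for both opposite pairs: 280 were higher and then lower (60 from independent lists), 95 lower and then higher (64.4), 27 higher both times (63.9) and 62 lower both times (60.6). The 89 genes had median log2 changes of 3.03 for D1 against D0 and -2.34 for D7 against D3. Their median for D7 against D0 was 1.17, so many remained above their D0 level. At D7 33 of them were called higher than at D0, 2 lower and 54 neither, and the lack of a call does not show a return to D0. Opposite changes numbered 108 in total, or 375 with the replicate number as a block, 175 with DESeq2 and 289 with no filter. They numbered 1 or 12 without D7 replicate 1 or 2, 3 or 2 without D3 replicate 1 or 2, 19 or 24 without D0 replicate 1 or 2, 38 or 69 without D1 replicate 1 or 2 and 252 or 253 without D5 replicate 1 or 2. None of the 10 named genes had both calls in every such fit.

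**Figure D5:**
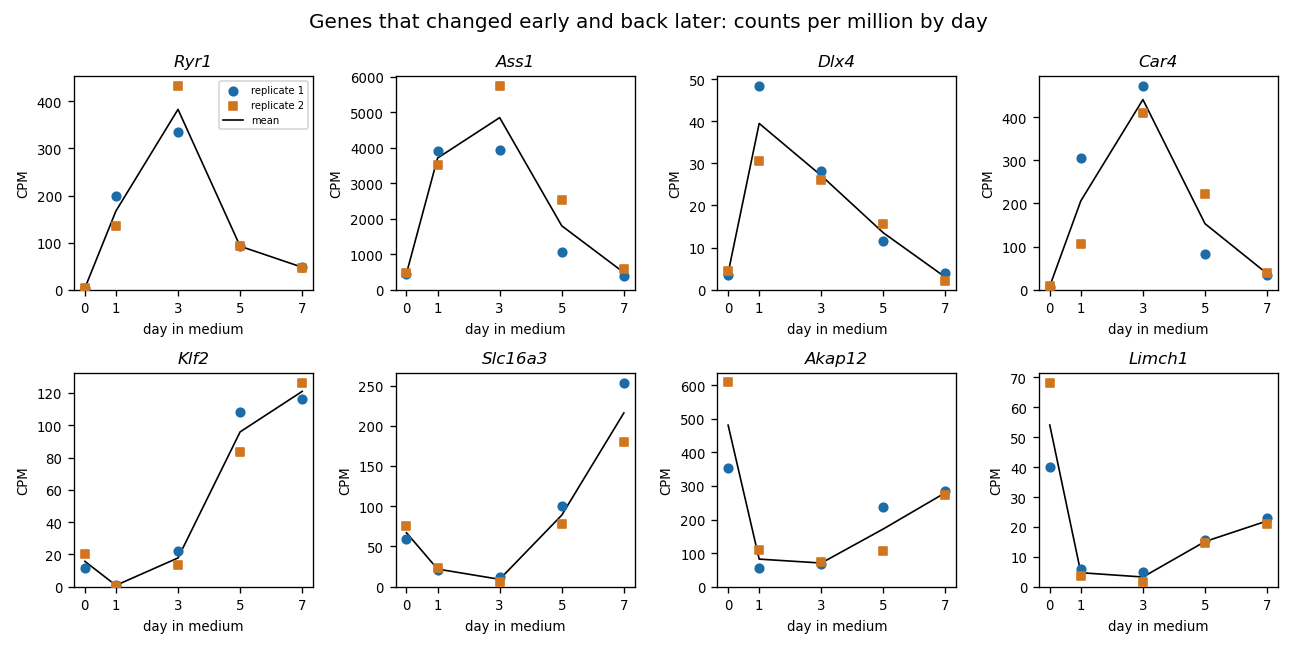
CPM (vertical axes, from 0) of 8 genes that changed early and in the opposite direction later, against day in the medium, 1 point per library (blue circles replicate 1, orange squares replicate 2) with a line through the means of 2. Ryr1, Ass1 and Car4 are highest at D3 (383, 4850 and 441 CPM), and Klf2 and Slc16a3 are lowest at D1 (0.812) and D3 (9.13).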

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

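The tests of library scaling, of depth and of the delivered factors were chosen only after the results they bear on had been seen. The other tests were written down after the patterns were seen but before their own values were. The 10 genes named for opposite changes early and late were taken up because the early and the late change differed. The D1 against D0 log2 change minus the D7 against D3 change was 8.68 for Ryr1, 6.34 for Ass1, 11.12 for Rph3a, 6.40 for Dlx4 and 8.24 for Car4. For Klf2, Limch1, Slc16a3, P4ha2 and Akap12 it was -6.82, -6.02, -6.09, -3.88 and -4.56. These genes were picked for 2 calls in opposite directions, so a test of the difference could hardly fail for them and none is given.

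The first pattern is the set of 89 genes that were higher at D1 than D0 and lower at D7 than D3. The pattern did not depend on the choice among TMM, RLE and upper-quartile scaling. With RLE and with upper-quartile scaling 87 or more such genes were found, where independent lists would share at most 6.75. For D7 against D0 these moved the median of all genes by only 0.02 and 0.13 (log2). A scaling error common to the methods could not be detected this way and stays open. A single replicate number as the source is argued against for such reversals over all tested genes, taken by size alone. In replicate 1 401 genes moved at least 2-fold up and then at least 2-fold down, and 516 in replicate 2. Of these 247 did so in both, where independent lists, which take no account of abundance, would share 16.2. For the 89 this adds little, since all 577 genes called for D1 against D0 moved the same way in both replicates. A transient response to the medium or to the delivered factors, of which Esrrb, Sall4 and Jdp2 were also called lower at D7 than at D3, may account for it, but the design has no library with the medium or the factors alone, so that stays an untested hypothesis.

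The second pattern is that pluripotency genes were higher in replicate 1 than in replicate 2 at D5, by a median log2 difference of 0.98 over 33 genes with 30 higher, beside 0.91 at D3 and 0.39 at D7. Depth as the whole source is argued against: thinning every library to the smallest total left a mean of 0.86 (SD 0.12 over 20 draws, beside 0.98), above the bound of 0.69 by more than 1 SD but less than 2, and it would stay open with a margin of 2 SD, the margin used at first; the draws were added after a first was seen and the 1 SD margin after all were. A library difference that is the same on every day cannot be told apart, since the D5 difference minus that at D7 (median 0.27, quartiles -0.20 and 0.79) or D3 (-0.33, -0.84 and 0.37) spread over both sides of 0, and the medians of 0 at D0 and D1, against it, come from days on which many of these genes were near the floor. Across all tested genes the D5 difference correlated with the D7 against D3 change at r = 0.49, beside 0.06 and 0.11 for the D0 and D1 differences, as would be seen if replicate 1 were further along the course at D5. Replicate 1 lay further along the first principal component on every other day too, so its position is not particular to D5. The labels give the replicates no property that could be tested as a biological explanation.

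The third pattern is the lower level of the delivered factors at D7 than at D3, called for 3 of the 4 and not for Glis1. The fall did not depend on the choice of scaling, since the median change of the 4 stayed at -1.81 or lower with RLE and upper-quartile scaling. A scaling error common to these methods and TMM could not be detected this way and stays open. Reads from the endogenous genes stay open: Esrrb and Sall4 had log2 changes of -1.65 or lower while the median pluripotency gene had 2.64, but the fall of both is the pattern itself, and whether their own copies follow that median was not measured. A loss shared by the 4 delivered transcripts stays open: their changes had an SD of 0.27, and a share of 0.233 of 10000 random sets of 4 falling genes of like abundance had an SD as small. Silencing of the viral promoters and outgrowth of cells with little virus could both give a shared loss, and these counts do not separate them.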

How the results depend on the processing

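All alternatives but the fit of protein-coding genes were chosen before the data were examined. That fit kept the counts for D7 against D0, D1 against D0 and D7 against D3 within 1.5 times, as did RLE scaling for every count and the 2-fold threshold for every count it was applied to. Upper-quartile scaling moved the median of all genes by 0.13 (log2) for D7 against D0. Over 19 settings, 204 changes of named genes gave 3499 values on the same side of the threshold with the same sign, 346 that lost the call, 10 that gained it and 21 that changed sign, and over 15 settings 35 lists gave 474, 33, 2 and 16 (lists were not run with upper-quartile scaling, DESeq2, limma-voom, the stricter filter, thinning or the days compared alone). With the replicate block the counts were 1350 (D1 against D0), 206 (D3 against D1), 421 (D5 against D3), 20 (D7 against D5), 3629 (D7 against D0), 2351 (D7 against D3), 4455 (any day) and 375 (early and late), and it ended no call. It changed no other call among named genes in D7 against D0 than those of Glis1 and Sfn, which were gained. With no filter they were 1064, 272, 452, 176, 1664 (D7 against D3), 4139 and 289. DESeq2 gave 128, 151 and 30 for D3 against D1, D5 against D3 and D7 against D5 and 175 early and late, limma-voom 1 and 4 for the first 2 of these. For D3 against D1, upper-quartile scaling gave 15, thinning 11 and the days compared alone 41; the last gave 1150 for D7 against D3. No list was called with an estimated correlation, 0 against 21. The first principal component held 47.4% with a larger set of variable genes and 49.3% with log2 TPM. Without each library in turn the counts ran from 120 to 908 (D1 against D0), 0 to 44, 0 to 295, 0 to 232, 841 to 2959 (D7 against D0), 4 to 1557 (D7 against D3), 1243 to 3494 (any day) and 1 to 253 (early and late); there a day keeps a single library, assumed to vary like the others. Fewer libraries lower the power, but that cannot give the higher counts without either D5 library for D1 against D0 or D7 against D3. Neither comparison uses D5, but all days share an estimate of the spread, so these counts depend on the spread between the D5 libraries. The D5 replicates differed most, with a chi-square per gene of 23 against 7.75 to 13.1 on the other days. Other causes were not tested.

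Changes of sign for genes (log2 change, D7 against D0) and of camera direction for lists were all of values not called in either fit, and the median of a list could keep its sign. Upper-quartile scaling gave 0.02 for Snai2, 0.06 for Twist1 and 0.10 for Atp5b, thinning 0.12, 0.03 and 0.06, and the stricter filter 0.02 for Atp5b. With no filter the camera direction turned for mitosis (median 0.16), mitochondrial (-0.01) and cartilage and bone genes (-1.16), and with the replicate block for the last (-1.08). Without each library Snai2 ran from -0.94 to 0.47, Twist1 from -0.77 to 0.44, Top2a from -0.17 to 0.32, Atp5b from -0.13 to 0.12, Atp5a1 from -0.05 to 0.35, Chd4 from -0.04 to 0.41, Hba-a2 from 0 to 6.36 and Krt15 from -1.19 to 0.09. List medians ran from 0.11 to 0.23 (mitosis), -0.09 to 0 (oxidative phosphorylation), -0.11 to 0.22 (NuRD), -0.6 to -0.25 (imprinted), -0.41 to 0.33 (LIF-STAT3), -0.16 to 0.19 (mitochondrial) and -1.27 to -0.89 (cartilage and bone). Of 21 lists called for D7 against D0, those of DNA replication, p53 and cholesterol genes were lost without some library. With fry those 3 were lost (adjusted p = 0.135, 0.076 and 0.14), as was AP-1 (0.214). BMP targets were gained without D7 replicate 2 and stress genes with no filter (0.0286). With no filter, where lists too small for the main test could enter, 12 lists were higher and 11 lower, beside 12 and 9 in the main fit. Depth limits the low genes, since 3 counts stood for up to 2.32 CPM.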

Other observations

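Markers of other lineages moved in a mixed way between D0 and D7. Of 11 extraembryonic endoderm markers 7 were higher and none lower (9 adjusted over the list alone, median log2 change 3.90, camera adjusted p = 6.17e-05, adjusted p = 0.263 with an estimated correlation). Here too, members silent at D0 passed the filter only through a later day, which favours a rise. Sox17, an endoderm transcription factor, was at least 18.6-fold higher, Rhox5, an X-linked homeobox gene, rose from 0.979 to 77.3 ± 19.2 CPM, and Foxa2 had a ratio of 48.1 (8.4 to 1920). Cubn, the cubilin receptor, stood at 94.8 ± 117 CPM at D7, with log2 changes of 6.29 in replicate 1 and 2.04 in replicate 2. Its call was lost without D7 replicate 1 or either D0 replicate, and with limma-voom (0.19). Without D0 replicate 1 the log2 changes of Rhox5 and Foxa2 were 10.59 (6.01 with it) and 8.04 (5.27). Of 11 endothelial markers 8 were higher and 2 lower (8 and 2 adjusted over the list alone, median 2.95, camera adjusted p = 0.0057, adjusted p = 0.213 with an estimated correlation): Pecam1, an adhesion molecule also made by pluripotent cells, had a ratio of 116 (31.8 to 959), and Cldn5, Tie1 and Esam were at least 19-, 7.73- and 9.57-fold higher. Primitive streak and mesoderm genes had 2 of 7 higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.193), with T, brachyury, at least 44.6-fold and Mixl1 at least 4.79-fold higher and Foxf1 lower. Trophoblast markers had 3 of 9 higher and 2 lower (3 and 2 adjusted over the list alone, 0.583), Tfap2c with a ratio of 71.5 (19.6 to 594) and Krt7 lower, and neural markers 2 of 6 higher and 1 lower (3 and 2 with the replicate number as a block, 2 and 1 adjusted over the list alone, 0.684), Stmn2 higher and Nes lower. The log2 change of Tfap2c ran from 5.35 to 9.65 over the alternative settings. Cartilage and bone markers had 2 of 9 higher and 2 lower (2 and 3 adjusted over the list alone, 0.97): Alpl, an alkaline phosphatase of bone and pluripotent cells, had a ratio of 235 (80.3 to 1140), and Runx2, a bone regulator, fell from 26.9 to 0.87 ± 1.23 CPM (log2 change -4.44, -8.87 without D7 replicate 1, and not called without D0 replicate 2, 0.0658).

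The remaining signalling, interferon, stress and imprinted groups had members called in both directions for D7 against D0. Imprinted genes had 3 of 19 higher and 2 lower (3 and 4 with the block, 3 and 4 adjusted over the list alone, camera adjusted p = 0.882), Nnat and Mest higher by 3.69 (SE 0.41) and 2.27 (SE 0.31) and Ndn lower by -2.10 (SE 0.41) on the log2 scale. Interferon-stimulated genes had 3 of 15 higher and 1 lower (5 and 1 with the block, 5 and 1 adjusted over the list alone, 0.344), Oasl2 and Bst2 higher and Ifit2 lower. BMP targets had 1 of 10 higher and 2 lower (1 and 4 with the block, 1 and 3 adjusted over the list alone, 0.334), LIF-STAT3 targets 2 of 8 higher and 1 lower (3 and 2 with the block, 3 and 2 adjusted over the list alone, 0.705), with Gbx2 and Socs3 higher and the cytokine receptor Osmr lower. FGF-ERK targets had 1 of 12 higher, Etv5 (46.1 to 235 ± 47.5 CPM), and 2 lower, Egr1 and Spry1 (1 and 2 adjusted over the list alone, 0.539). Stress response genes had 1 of 15 higher, Asns (79.5 to 246 ± 3.82 CPM), and 2 lower, Atf5 and Hspa5 (1 and 4 with the block, Hspa5 not called with upper-quartile scaling, 0.0645, 1 and 2 adjusted over the list alone, 0.242). In the lists too small to test, the muscle genes Mylpf (ratio 175, 48.2 to 1450) and Tnnt1 (at least 8.65-fold) were higher while Acta1 and Des were lower (log2 changes -5.41 and -3.75), and the adipocyte list had Lpl higher (6.79 to 32.4 ± 4.32 CPM) and Cebpa lower. The log2 change of Mylpf ran from 6.52 to 10.82 over the alternative settings, and Tnnt1 did not keep its call without each library. No macrophage, erythroid or keratinocyte marker was called, Lyz2 standing at 8.13 and 2.73 ± 1.07 CPM. Sfn, of the keratinocyte list, had an adjusted p of 0.059, or 0.0321 with the replicate number as a block, and was called in 8 of 19 alternative settings. Of the 120 called list members that the rule for named genes picked, 58 remained called without each library.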
